A study of Mus musculus with 2 samples.

How the data were processed

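RNA of mouse B cells labelled miR-155 knockout or wild-type was hybridised to Affymetrix 3′ expression arrays, 1 array per genotype. Biotin-labelled cRNA was made with the Affymetrix 3′ IVT Express kit from Trizol-extracted total RNA, per the labels' protocols. The same protocols state that cells received cycloheximide at 100 ug/ml for 8 min before harvest. Cycloheximide is an inhibitor of translation elongation.

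The deposited table holds log2 intensities for 45101 probe sets on the 2 arrays, between 3.09 and 15.4. The log2 unit was read from these values, and the summarisation and normalization that the authors used are not given in the sources used here. The sorted values of the arrays differed by at most 0.063, so the authors had brought them to nearly the same distribution before deposit. A difference in total RNA per cell between the genotypes would therefore not be visible. Hybridisation controls (18 probe sets) had a median difference of -0.09 and labelling controls (24 probe sets) one of 0.09. All differences are given as the array labelled knockout minus the array labelled wild-type, on the log2 scale.

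Probe sets were named from the platform's annotation table, whose symbols were checked through Entrez numbers against mouse RefSeq genes of GRCm38.p6. A single gene was listed for 34945 probe sets, several genes for 932 and no gene for 9160, and 64 were array controls. Of the probe sets with a single gene, 34741 matched by Entrez number and 0 symbols changed. Each gene took the value of its probe set with the highest mean over both arrays, which gave 18193 genes. A gene counted as expressed where that mean was at or above 6.71, the median of all probe sets that are not controls, and 10717 genes passed. Symbols in the gene lists that matched no singly named probe set were not analysed here.

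With 1 array per genotype no spread between animals or cultures can be estimated, so no p-value was computed, no array could be left out, and the number of arrays limits the precision. As a technical yardstick, 2 expressed probe sets of the same gene disagreed in their log2 difference by a median of 0.084 and by 0.31 at the 95th percentile, over 4906 genes. Gene lists were fixed before the data were examined, from textbook knowledge and remembered literature. For each of the 29 lists the median log2 difference of the expressed members was compared with 10000 random lists of the same size, drawn from expressed genes and matched on mean level in 10 bins. A list stood apart where its median lay below the 2.5th or above the 97.5th percentile of the random medians, which describes these 2 arrays and is not a test of genotype. Genes of a list are regulated together, so such percentiles come out extreme more often than for unrelated genes. By chance 1.45 of 29 independent lists would stand apart.

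The genes named in the text followed a rule that was also fixed before the data were examined. It takes the 15 highest and 15 lowest differences among expressed genes whose other expressed probe sets all differed in the same direction, leaving out unnamed clones. It adds the 2 highest and 2 lowest expressed members of each list, Mir155hg, and each reported miR-155 target that differed by 0.5 or more. Other genes are marked as chosen after their values were seen.

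On simulated data for this comparison, 10717 genes took differences drawn from real ones that lay within 0.5 of the median. Of these genes 200 were then shifted by 1.5. At 2-fold, 100% of the shifted genes were recovered and 0 unshifted genes were called. Both results followed from this setting, since no unshifted gene could reach 2-fold and every shifted gene had to. They do not measure false calls in the real data. Of 200 simulated lists of 25 genes, 3.5% stood apart without a shift and 100% after a shift of 0.2. The list results rest on the same drawn differences, without the tails of the real ones. The alternatives were the mean of a gene's probe sets, only probe sets with a plain _at suffix, quantile normalization, subtraction of a loess curve of difference on level (span 0.3), no filter on low values, and a filter at the 75th percentile. The planned pseudocounts did not apply to values that were already log2, and the planned search for miR-155 sites in 3′ untranslated regions was not run because no transcript sequence was used here. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.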

Results

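Gene expression was profiled in cultured and activated mouse B cells with and without miR-155, a microRNA that is induced when B cells are activated. The series holds 2 arrays, 1 labelled knockout and 1 labelled wild-type, and asks which transcripts differ between the genotypes. The labels contradicted each other. The titles and the genotype entries gave this assignment, and the source names gave the opposite assignment for both arrays. Groups follow the titles and genotype entries, each array is called by that label, and if the source names are right every sign below turns over. Because there are no replicates, each value is a single measurement, no difference could be tested against replicate spread, and differences are described by their size. The log2 intensities of the arrays had medians of 6.701 (labelled knockout) and 6.718 (labelled wild-type) over probe sets that are not controls and correlated at r = 0.997 across all probe sets, which are not independent replicates.

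Mir155hg, the host transcript from which miR-155 is processed, lies on mouse chromosome 16 and was read by a single probe set. Its level was 10.88 on the array labelled knockout and 6.63 on the array labelled wild-type. It was thus higher on the array labelled knockout by 4.25, the largest difference among the 10717 expressed genes. Because the lower level was under 6.71, the level at which a gene counted as expressed, the fold is given as a bound against that level, at least 18.0-fold. The level on the array labelled wild-type lay at percentile 48.7 of that array's probe sets, and the level on the other array at percentile 91.1. The targeted gene therefore went against the genotype label. Where the probe set lies relative to the deleted part of the gene was not determined here, and a probe set outside that part does not check the label. Both arrays were labelled as male animals, and Eif2s3y, a Y-linked gene, had levels of 10.67 and 10.59.

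Transcripts reported or predicted as direct miR-155 targets were lower on the array labelled knockout. Of 44 expressed members of the target list, 36 were lower and 8 higher, and the median difference was -0.23, below all 10000 random lists matched on level (central 95% from -0.01 to 0.08). Sites for the microRNA were not searched here, so the list rests on the literature alone. The members that differed by 0.5 or more were all lower. They were Pmaip1 (-1.34), which encodes the pro-apoptotic protein NOXA, Bach1 (-1.06), a haem-regulated transcriptional repressor, and Jarid2 (-0.91), a component of Polycomb complexes. Spi1 (-0.89), the transcription factor PU.1, Tspan14 (-0.86), Zfp652 (-0.81), the GTPase gene Rheb (-0.67) and the helicase gene Dhx40 (-0.62) completed this group. Inpp5d, the phosphatase SHIP1, differed by -0.36 and Socs1 by -0.29, both chosen after their values were seen. The highest members were Msh6 (0.35), a mismatch repair gene, and Pik3r1 (0.25). The 2 expressed probe sets of Bach1 differed by -1.06 and -0.34.

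**Figure D1:**
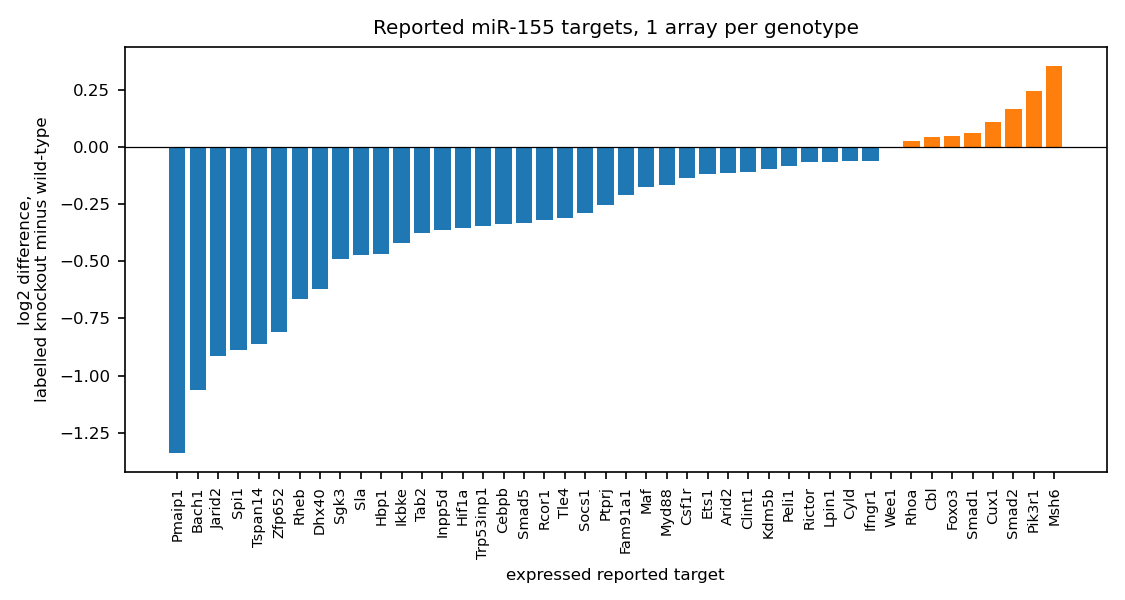
Log2 difference (array labelled knockout minus array labelled wild-type, y axis) of the 44 expressed reported miR-155 targets (x axis, sorted), 1 bar per gene from 1 array per genotype, without error bars because there are no replicates. The bars of 36 genes lie below 0, down to -1.34 for Pmaip1, and those of 8 genes above it.

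Across the transcriptome the arrays were close. The difference had an SD of 0.19 over expressed genes, and its central 95% ran from -0.39 to 0.37. Only 17 expressed genes differed by 2-fold or more, 2 higher and 15 lower on the array labelled knockout, and 73 were higher and 140 lower by 0.5 or more. Of 82 such genes with several expressed probe sets, 70 had all of them in the same direction. Under the same-direction rule, the genes that were lowest on the array labelled knockout included Oasl2 (-1.63) and Ifi204 (-1.51), which are interferon-induced, Il7r (-1.60), the receptor chain for interleukin 7, and Mmp13 (-1.59), a collagenase. They also included the tripartite motif genes Trim30d (-1.48), Trim12a (-1.46) and Trim5 (-1.31), the cytokine gene Il1a (-1.22), and Prdm1 (-1.19), which encodes Blimp-1, the main driver of plasma cell differentiation. The chemokine gene Cxcl10 (-1.05), the haem oxygenase gene Hmox1 (-1.03), Adam8 (-0.98) and the quinone oxidoreductase gene Nqo1 (-0.96) followed. On the array labelled knockout Mmp13 and Il1a lay below the level at which a gene counted as expressed, so against that level they were at least 2.32-fold and 2.33-fold lower. The probe sets of Trim12a differed by -1.46 and -0.24, and Trim genes are close paralogs whose probes may be shared.

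Among genes whose expressed probe sets all differed in the same direction, the highest on the array labelled knockout after Mir155hg was Cdc6, a licensing factor of DNA replication (1.09, 2.13-fold). It was followed by Mid1 (0.93), Eps8 (0.84), Ift81 (0.84), the zinc finger gene Egr2 (0.83), Spib (0.81), an ETS factor of B cells, Scd2 (0.80), a stearoyl-CoA desaturase, and Xrcc5 (0.80), which encodes the Ku80 subunit of the end-joining machinery. Mfsd4a (0.79), Ccdc34 (0.79), the chemokine receptor gene Ackr3 (0.74), Akap12 (0.72), Tnfrsf21 (0.72) and Sbk1 (0.70) completed the highest 15. On the array labelled wild-type Ift81, Mfsd4a, Ackr3 and Tnfrsf21 were below the level for expression, and their bounds against it were at least 1.42-fold, 1.42-fold, 1.66-fold and 1.31-fold, so their rank is uncertain. The 3 expressed probe sets of Scd2 differed by 0.77 to 0.80, and Mid1 was 0.20 rather than 0.93 when all its probe sets were averaged.

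**Figure D2:**
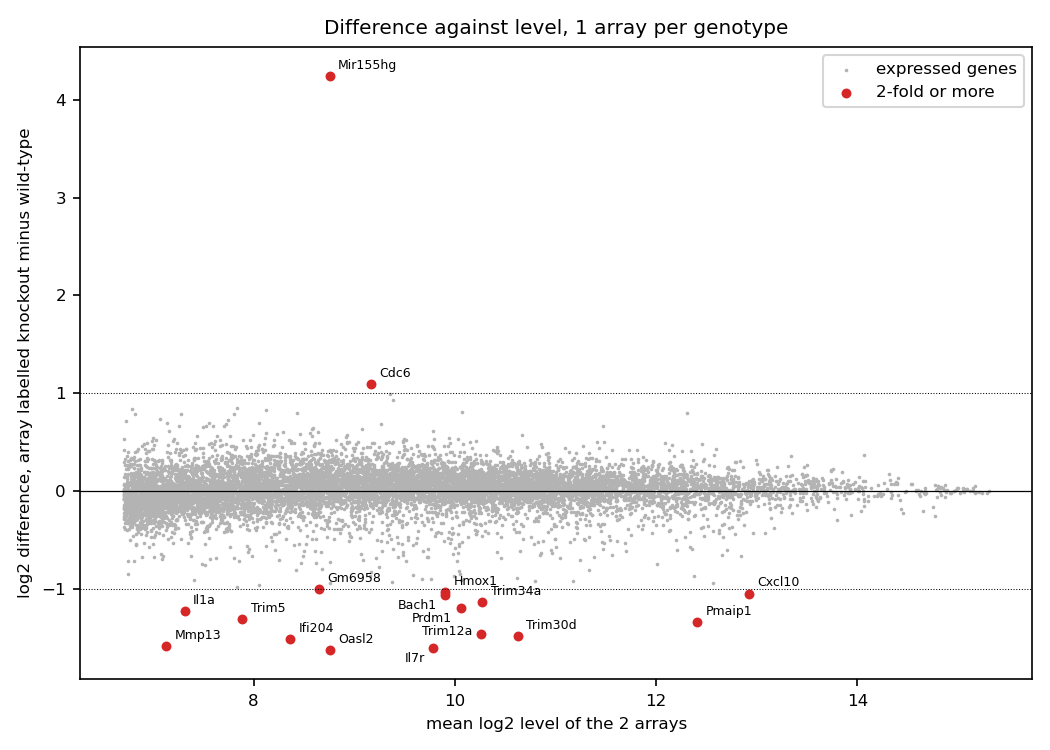
Log2 difference (array labelled knockout minus array labelled wild-type, y axis) against the mean log2 level of the 2 arrays (x axis), with 1 grey point per expressed gene and the 17 genes at 2-fold or more in red and named. Mir155hg stands alone at 4.25, and 15 of the other 16 red points lie at -1 or below.

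Genes of cell division were slightly but almost uniformly higher on the array labelled knockout. In the S phase and DNA replication list 27 of 30 expressed members were higher, with a median of 0.27, led by Cdc6 and by Pola1, the catalytic subunit of DNA polymerase alpha (0.50). Cdt1 (-0.26) and Gins1 (-0.10) were lower. In the G2/M list 26 of 27 members were higher, with a median of 0.27, led by the mitotic kinesin gene Kif11 (0.66) and the kinase gene Nek2 (0.52), and Kif2c stood at -0.21, a direction that turned to 0.14 with plain _at probe sets only and to 0.05 with the mean of its probe sets. In the list of MYC targets and ribosome biogenesis 27 of 28 members were higher, with a median of 0.20, led by the nucleolar phosphoprotein gene Nolc1 (0.41) and by Cad (0.38), the initiating enzyme of pyrimidine synthesis. The medians of all 3 lists were above all 10000 random lists. Only 3 members across these lists differed by 0.5 or more.

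Sterol synthesis genes were also higher. All 20 expressed members of the cholesterol biosynthesis list were higher on the array labelled knockout, with a median of 0.28 that was above all 10000 random lists. The highest were Dhcr7 (0.64), a reductase at the end of the pathway, and the lanosterol synthase gene Lss (0.51), and the lowest were Pmvk (0.05, and just below 0 after a loess curve was subtracted) and the regulator gene Srebf2 (0.11). By contrast the glycolysis and hypoxia list had a median of -0.10, with 19 of 24 members lower, at percentile 0.01. Its lowest members were Egln3 (-0.77), a hypoxia-induced prolyl hydroxylase, and the MYC antagonist gene Mxi1 (-0.43), and its highest were Ankrd37 (0.43) and Vegfa (0.18). Oxidative phosphorylation genes (median 0.04, 29 members) and cytosolic ribosomal protein genes (median 0.02, 23 members) lay inside the random range.

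Interferon-response genes were lower on the array labelled knockout. Of 31 expressed members 30 were lower, with a median of -0.28 that was below all 10000 random lists. Oasl2 and Cxcl10 were the lowest, and Oasl1 (0.02) and the immunoproteasome gene Psmb8 (-0.01) the highest, both so near 0 that their sign turned under an alternative. Immediate early genes had a median of -0.11, with 22 of 28 members lower, below all 10000 random lists. Among them Nr4a2 (-0.41) and Klf6 (-0.38) were the lowest, and Egr2 (0.83) and Dusp6 (0.23) the highest. The list of activation and NF-kB genes had a median of -0.06 at percentile 0.11, with 18 of 29 members lower, among them the chemokine gene Ccl3 (-0.73) and Slamf1 (-0.45). Batf (0.32), a factor needed for class switching, and Tnf (0.23) were its highest members. With only plain probe sets this list no longer stood apart (median -0.02). Markers of macrophages and monocytes (median -0.18) and of dendritic cells (median -0.22) were also lower on this array.

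B cell identity genes were higher on the array labelled knockout. Of 25 expressed members 21 were higher, with a median of 0.17, above all 10000 random lists. Markers of macrophages and dendritic cells moved the other way, so the share of B cells on each array is not separated from this difference. These markers are a weak measure of that share. Several macrophage markers lay near the level for expression. The dendritic cell list shares Bst2 with the interferon list, and 2 of its 8 expressed members were higher. Spib (0.81) and the kinase gene Blk (0.50) were the highest, and Bank1 (-0.18) and the chemokine receptor gene Cxcr5 (-0.18) the lowest. In the class switch and somatic hypermutation list 14 of 15 members were higher, with a median of 0.21 at percentile 99.98, led by Xrcc5 and by Ung (0.46), the uracil glycosylase that processes deaminated bases, while Rnf8 was -0.32. Several of its members are also general DNA repair genes.

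Lists of B cell differentiation did not stand apart in the main comparison. The plasma cell program had a median of 0.05 over 15 members, although it held Prdm1 (-1.19) and the immunoglobulin J chain gene Jchain (-0.56) at its low end and Slamf7 (0.45) at its high end. The germinal centre program had a median of -0.07 at percentile 2.85, with Basp1 (-0.50) and Bcl6 (-0.35), the master repressor of that stage, at its low end and Plxnb2 (0.31) at its high end. The interleukin 4 response (median 0.02), the unfolded protein response (median 0.05), MHC class II presentation (median 0.09), the p53 response (median 0.04) and TGF-beta signalling (median -0.01) lay inside the random range. Under the 6 alternatives the germinal centre list stood apart 4 times (percentile down to 0.83), the MHC class II list 2 times (percentiles 98.19 and 98.66) and the TGF-beta list 1 time (median -0.06, percentile 1.28). Within these, the low-affinity IgE receptor gene Fcer2a differed by 0.37, the chaperone gene Calr by 0.35, H2-DMb2 by 0.29, the cell cycle inhibitor gene Cdkn1a by -0.60 and Ski by -0.46.

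**Figure D3:**
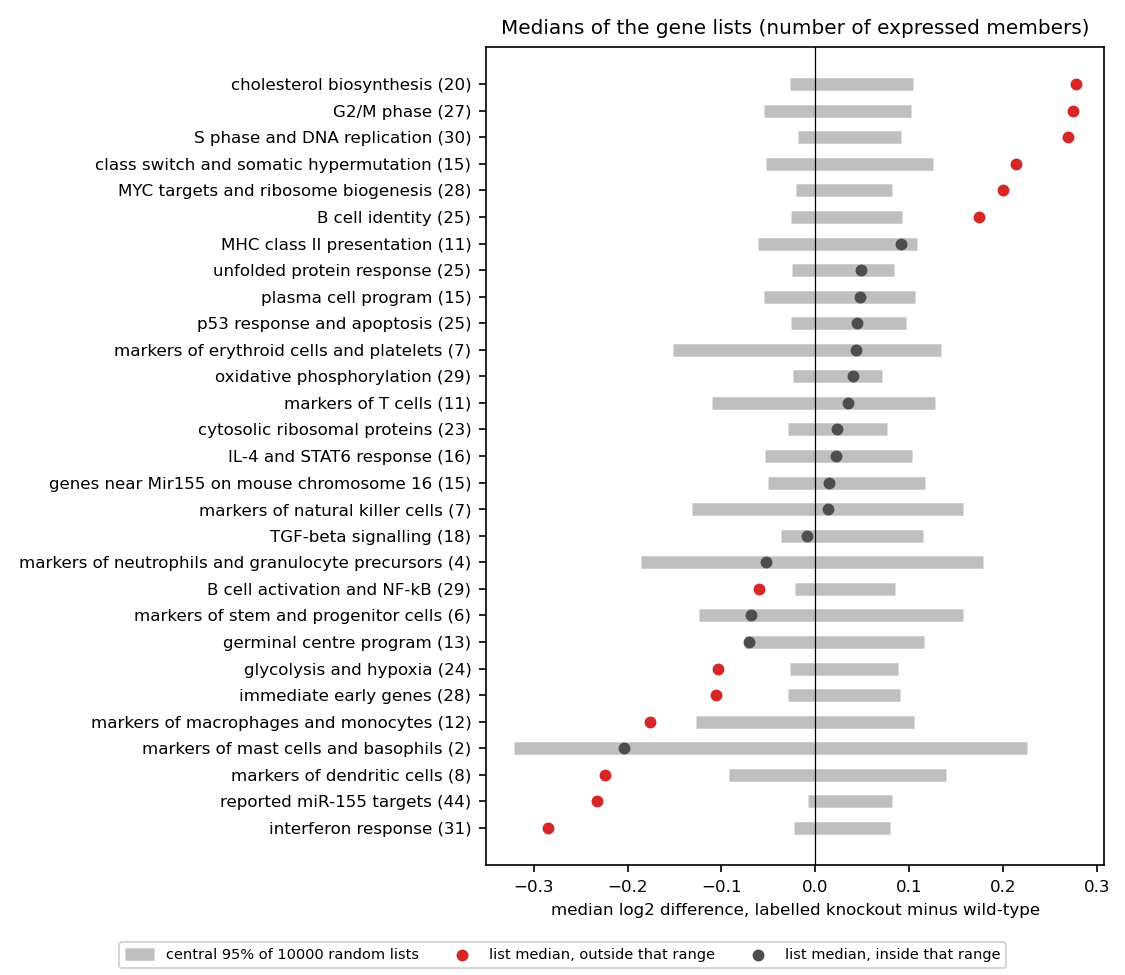
Median log2 difference (x axis, array labelled knockout minus array labelled wild-type) of the expressed members of each of 29 gene lists (y axis, with the number of members), as points over grey bars that span the central 95% of 10000 random lists matched on level. Of the 13 medians outside their bar, 6 lie above it and 7 below, from -0.28 for interferon response to 0.28 for cholesterol biosynthesis.

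The labels also described the culture in different ways, as B cells and as progenitors grown with G-CSF and stem cell factor for 6 days, so markers of both were examined. All 25 measured B cell identity genes were at or above the array median on each array. Of 22 measured markers of neutrophils and their precursors 4 were, namely Camp (-0.07), Prtn3 (-0.05), Lcn2 (-0.05) and Gfi1 (0.16). These counts go with the B cell label and argue against a culture made up mainly of neutrophils or their precursors. Of 15 measured stem and progenitor markers 6 were at or above the median level, among them Slamf1 (-0.45), Flt3 (-0.27), Lmo2 (0.17) and Myb (0.10). The progenitor count does not settle whether such cells were present. Macrophage and monocyte markers had a median of -0.18 over 12 expressed members of 23 measured, at percentile 0.33, with Tyrobp (-0.39) and Cd14 (-0.35) lowest and Ccr2 (0.06) highest. Dendritic cell markers had a median of -0.22 over 8 members of 15, at percentile 0.03, with Zbtb46 (-0.44) and Bst2 (-0.31) lowest and Batf3 (0.37) highest. Markers of T cells (median 0.04), natural killer cells (0.01), mast cells and basophils (-0.20, 2 members) and erythroid cells and platelets (0.04) did not stand apart. The progenitor list stood apart under 3 alternatives and the natural killer list under 1, and the macrophage list no longer stood apart with the filter at the 75th percentile of levels (percentile 4.58). Single members of these lists did differ, such as Il7r (-1.60), Cd2 (0.66) and Thy1 (0.56) among T cell markers and the chemokine gene Ccl5 (-0.92) among natural killer markers.

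Genes that neighbour Mir155 on chromosome 16 did not differ as a group. The 15 expressed members of that list had a median of 0.02 at percentile 31.7. Bach1 (-1.06) and the corepressor gene Nrip1 (-0.68) were the lowest and Mrpl39 (0.24) and Gabpa (0.21) the highest. Thus 2 of the 15 were lower by 0.5 or more, against 140 of all 10717 expressed genes, and Bach1 is also on the target list. The 5 expressed probe sets of Nrip1 ranged from -0.69 to 0.74, so its direction depended on the probe set.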

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

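The gene list medians, the loess alternative, the Mir155hg levels and the 3′ minus 5′ control values in this part were planned before the data were examined, while the tests on gene runs and Trim genes, and the use of every value here as a test of an explanation, were chosen after the results were seen. Among the 3348 expressed probe sets that name no single gene, which no comparison used, 3 differed by 2-fold or more, all of them lower on the array labelled knockout.

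The direction of Mir155hg and of the reported miR-155 targets went against the genotype labels. Loss of a microRNA is known to raise its direct targets, yet on the array labelled knockout the host transcript was higher by 4.25 and the target list had a median of -0.23. The tables argue against correct labels with a probe set outside the deleted part, because the targets would then be higher on the array labelled knockout, and their median of -0.23 was below all 10000 random lists. Correct labels with a less activated culture on the array labelled wild-type stay open, because the rows point both ways. Against it, activation genes had a median of -0.060 at percentile 0.11, although 11 were higher and 18 lower and the list no longer stood apart with plain _at probe sets only (median -0.02, percentile 4.98), and immediate early genes had a median of -0.11 with 22 of 28 lower on the array labelled knockout. With it, S phase (0.27), G2/M (0.27) and MYC target genes (0.20) were higher there. The opposite assignment was known from the source names before the data were examined, and an exchange of the labels would need a higher Mir155hg (4.25) and lower targets on the array labelled knockout. Both are there, and either could have come out the other way. It stays a hypothesis, because 1 array per label cannot show which animal was used.

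Neighbouring genes differed together in a run on chromosome 7, but only with some probe sets. The lowest run of 7 consecutive expressed genes held Trim68, Trim34a, Trim5, Trim12a, Trim12c, Trim30a and Trim30d and had a median of -1.14, and 0 of 1000 shuffles of the differences over 10679 gene positions held a run as low (lowest -0.67). With plain _at probe sets only, the 5 Trim genes left of the 6 after Trim68 had a median of -0.24 instead of -1.22, and 948 of 1000 shuffles held a run as low as the lowest with a Trim gene (-0.24), so chance placement stays open and the pattern depends on the probe set. The plain sets of Trim34a and Trim12a had mean levels of 7.09 and 7.32, near the level for expression, against 10.27 and 10.26 for the sets they replaced. Trim5 (-1.31) and both sets of Trim30d (-1.48 and -1.43) are plain and stayed low, while Trim12c (-0.01) was not low. A segment carried along with the targeted Mir155 locus is argued against for this run by its chromosome. The median of the genes near Mir155, at percentile 31.7, does not decide this, because such a segment could alter single genes. A lower interferon response alone stays open, since 1 of 31 interferon genes was as low as the median of these Trim genes but they were picked for their low values. Probes shared between paralogs, a splice form or a strain difference may also act here, untested.

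Division and sterol genes were higher and interferon genes lower on the array labelled knockout. A trend of the difference with signal level is argued against by its size, since the loess curve lay between -0.046 and 0.055. The list medians were 0.27 for S phase, 0.27 for G2/M, 0.28 for cholesterol and -0.28 for interferon. After the curve was subtracted, 4 of the 4 lists stayed outside the random range. With so small a curve this had to be so, and it adds no separate support. RNA quality is argued against, since the 3′ minus 5′ difference of the Actb and Gapdh controls differed between arrays by at most 0.014. More macrophages or monocytes on the array labelled wild-type may account for part of the interferon difference. Macrophage and monocyte markers had a median of -0.18, smaller in size than the interferon median of -0.28 and than Oasl2 at -1.63. Of the 12 expressed markers 9 were lower and 3 higher. Lyz2 (6.88 on the array labelled knockout, 7.12 on the other), Cd68 (6.88, 7.12) and Cd14 (6.85, 7.21) lay near the level for expression. Tyrobp (8.97, 9.36) lay further above it and was lower too. Markers near that level measure a share of cells poorly, so the share of such cells is unknown and this stays open. B cell identity genes (0.17) were higher where markers of macrophages (-0.18) and of dendritic cells (-0.22) were lower. A different share of B cells would give this, while markers of T cells (0.04) and natural killer cells (0.01) went both ways. The dendritic cell markers Irf8 (13.50 on the array labelled knockout, 13.67 on the other), Bst2 (11.81, 12.12) and Ly75 (11.48, 11.32) had levels within the range of the B cell identity genes. Which cells they came from was not determined, so the dendritic cell list is a weak measure of the share of cells. A different share of B cells therefore stays open too. Genotype and a difference between the cultures remain open and cannot be told apart with 1 culture per genotype.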

How the results depend on the processing

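No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Under the 6 alternatives, 11 of the 13 gene lists that stood apart did so each time. The exceptions were activation and NF-kB genes with plain _at probe sets only (median -0.02, percentile 4.98) and macrophage markers with the filter at the 75th percentile of levels (median -0.18, percentile 4.58). No list that stood apart changed sign under any alternative. The target list median ran from -0.29 to -0.21. It moved to -0.28 after loess, a move within the size of the curve that was subtracted (up to 0.055). With that filter it moved to -0.29, and the cause was not tested. Over the 35 targets found in no other list, a choice made after seeing the data, it was -0.21. With the same filter, 1 gene was higher and 9 were lower by 2-fold or more, because fewer genes were considered (6306), while the p53 list moved to -0.017, natural killer markers to -0.21 and progenitor markers to -0.27, both marker lists over 3 members. With the mean of a gene's probe sets, the S phase list moved to 0.21 and progenitor markers to -0.27; the cause was not tested. Lists inside the random range gained a call as follows: germinal centre under 4 of 6 alternatives, progenitor markers under 3, MHC class II under 2, and TGF-beta and natural killer markers under 1 each. Of 727 values of 135 named genes under these alternatives, 723 moved by less than the central spread of all genes, 4 by more (Mid1 to 0.20, Trim12a to -0.85 and -0.24, Nrip1 to -0.27), and 0 of those that differed by 0.5 or more changed sign. The sign turned in 12 named genes, each at 0.21 or less from 0. Also after seeing the data, the interferon list without Trim30a had a median of -0.28, and B cell identity without Spib 0.17. Depth on arrays is signal over background: levels near the median, such as Mir155hg on the array labelled wild-type, may compress differences, which was not tested.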

Other observations

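The lists in this part were written after the values were seen, and each was prompted by genes that are left out of the second value given. The values of the remaining members were open to view as well, so their percentiles describe the lists and are not independent support. Cad, in the purine and pyrimidine list, is also in the list of MYC targets. Genes of fatty acid synthesis and desaturation were higher on the array labelled knockout, with 13 of 14 expressed members higher and a median of 0.35. Without Scd2, Fads1 and Fads2 the median was 0.22 over 11 genes, at percentile 99.99 of random lists, with Scd1 at 0.50, the fatty acid synthase gene Fasn at 0.41 and Acaca at 0.36. Purine, pyrimidine and one-carbon synthesis genes had 14 of 16 members higher, and without Atic a median of 0.24 that was above all 10000 random lists, with Pfas at 0.51 and Adss at 0.47. Homologous recombination and Fanconi anaemia genes had 12 of 13 members higher, and without Rad51ap1 and Fancb a median of 0.21 at percentile 99.79, with Brip1 at 0.52 and Palb2 at 0.43.

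Antioxidant genes under the control of NRF2 and BACH1 were lower on the array labelled knockout in 11 of 12 expressed members. Without Hmox1 and Nqo1 their median was -0.24, below all 10000 random lists, with the glutathione reductase gene Gsr at -0.87, Srxn1 at -0.56 and Txnrd1 at -0.50. Bach1, a repressor of Hmox1, was itself lower on this array (-1.06), so repressor and repressed gene were both lower. All 5 expressed Schlafen genes were lower, from Slfn1 (-0.90) to Slfn9 (-0.09), and without Slfn1 the median was -0.31 over 4 genes, at percentile 0.1. With plain _at probe sets only, the run of 7 neighbouring genes that holds these 5 was the lowest of all, with a median of -0.32. However, 299 of 1000 shuffles held a run as low. Among runs of 7 neighbouring expressed genes, the highest median was 0.47 on chromosome 1, where the consecutive genes Atic (0.67), Mreg (0.49), Pecr (0.47) and Xrcc5 (0.80) were all higher, and 1 of 1000 shuffles gave a run as high. The other 3 genes of that run were Kansl1l (-0.33), Acadl (-0.01) and Lancl1 (0.12). Xrcc5 and Atic are therefore also neighbours, in addition to their places among repair and purine genes.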
